A study of Mus musculus with 12 samples.

How the data were processed

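The series deposited small-RNA sequencing of mouse embryonic stem cells, 12 libraries of 1 file each. RNA of 18 to 75 nt was cut from a gel. Per the labels, 8 libraries were made by circularization, which takes RNA with or without a 5' phosphate, and 4 by ligation with the NEBNext kit, which needs one. Each deposited file lists distinct read sequences with the raw count of reads in the second column, and the authors did not normalise these counts. How reads were trimmed is not given in the sources used here. The longest reads were 50 nt in the libraries of replicate A, 51 nt in those of replicate B and 40 nt in the other 4, so the code also marks a sequencing run type. Values within a code are given beside the hairpin and window shares of the IPs, but not beside every pooled value.

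No genome sequence was given, so reads were matched to the transcripts of the GENCODE vM21 annotation (GRCm38), with 55450 genes and 141767 transcripts. A distinct sequence of 18 nt or more without N (14231291 sequences over all libraries) had to match a transcript exactly, on its strand and over its whole length. Reads inside 1 of 2202 miRNA genes were hairpin reads; a sequence found in several hairpins was counted for a merged feature that names them all with a slash. Other small-RNA genes came next in priority. A promoter-proximal read had its 5' end in the first 200 nt of any transcript of 1 of 21951 protein-coding genes, in spliced coordinates, and its sequence in no other gene. The plan held 50 nt upstream of the start and uniqueness in the genome, but neither can be searched without a genome. Nuclear tRNA and 45S rRNA are not in the annotation as genes of their own and were not analysed as such. The rRNA class holds the annotated rRNA genes and a few non-coding genes that overlap 45S rRNA repeats. Exact matches covered 11.0 to 60.9% of reads, reads under 18 nt 5.21 to 23.2%, and reads that reached the read end 0.985 to 23.7%.

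CPM values scale the counts of a file to a sum of 1000000 over all its reads. A share of 0 allows up to 3 counts of the total, and PCR copies cannot be told from separate molecules, so intervals and floors cover counting error only. Within groups the 2 libraries differed beyond counting noise (chi-square per degree of freedom 83.1 to 746), with correlations of log2 CPM of 0.952 to 0.985 for hairpins and 0.790 to 0.830 for windows across features, which are not independent replicates.

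The 4 replicated groups were fitted together in edgeR 4.0.16 (R 4.3.3) with quasi-likelihood F tests, 1 coefficient per group, library totals without further factors, filterByExpr at its defaults, and Benjamini-Hochberg adjustment within hairpins and within windows at 0.05. There were 4 contrasts for each of the 2 classes. Groups of 2 libraries are too small for a spread of their own, so the fit shares it. Lists were tested with camera (preset correlation 0.01, then estimated) and fry in limma 3.58.1 on log2 CPM with a prior count of 2. DESeq2 1.42.0 with its own size factors was the other tool. Shares and read lengths were compared with exact two-sided permutation tests in scipy 1.17.1. Single libraries were compared by ratios of shares with exact binomial intervals (Clopper-Pearson, 95%) and no test; a list's median was placed among 10000 random lists of equal size drawn from the 50 features nearest in abundance to each member. Matching and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and plots matplotlib 3.10.9.

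Named genes were fixed by a rule set before the data were examined, as were the groups, the contrasts, the lists and most of the other settings. Of features past the threshold, with a mean of at least 10 CPM (hairpins) or 1 CPM (windows) and both libraries of 1 group above both of the other, the 10 largest increases and the 6 largest decreases qualify. The 3 most abundant measured members of each list qualify too, and Ago2 and Dicer1 always. In single libraries the 8 highest and 8 lowest ratios with at least 100 reads and 3 members per list qualify. The text gives a part of these.

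The 22 lists were 14 of miRNAs (miR-290-295, miR-302, miR-17-92 and paralogs, let-7, Dlk1-Dio3, the Sfmbt2 intron cluster, mirtrons and start-site hairpins, miR-451, abundant miRNAs, and miRNAs of fibroblast, muscle, liver, neural and blood cells) and 8 of window genes (pluripotency, ribosomal protein, histone, immediate-early and stress, Polycomb-target developmental, small RNA pathway, snoRNA host and housekeeping).

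Simulated counts were drawn at each feature's mean level, with 1 assumed spread for all features in place of the spread of these libraries. The fit was tested on known changes in these counts. Of 4-fold changes it recovered 47 of 50 in hairpins (620 tested) and 35 of 49 in windows (786 tested), and of 2-fold changes 13 of 50 and 11 of 50, with 3 false calls among 520 unchanged hairpins and 1 among 687 unchanged windows. Other settings chosen beforehand were TMM factors, DESeq2, no filter on low counts, the replicate code as a block, only the libraries of a contrast, leaving out each library, other read lengths, a window to 100 nt, sequences in up to 10 genes, distinct sequences in place of reads, and other totals. Settings added after seeing the data were scaling to reads outside miRNA hairpins, 1 extra 5' base, reads of 22 nt or more, windows without 1 dominant 5' end, and 20 to 24 nt for the single-library hairpin ratios. Substitutions were searched by comparing reads with the first 21 nt of a window's main sequence, or all of it where shorter.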

Results

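Small RNAs of mouse embryonic stem cells were sequenced in 12 libraries. In 8 of them, and in a single library named below, the cells made Ago2 from a gene switched on by doxycycline at 2.5 µg/mL. Ago2 is the protein that carries miRNAs to their targets. The TT-FHAgo2 line made it with FLAG and HA tags and the TT-Ago2 line without a tag. From each line there were 2 libraries of RNA pulled down with a FLAG antibody (IP) and 2 of the starting RNA (input), all cloned by a protocol that does not need a 5' phosphate. The titles give each replicate 1 of 2 codes; libraries of the code with reads of up to 50 nt are called replicate A and those of the code with up to 51 nt replicate B. Cloning that needs a 5' phosphate gave 4 single libraries: TT-FHAgo2 cells with doxycycline, the same line without it, wildtype cells and Dicer-null cells, which lack the enzyme that releases most miRNAs from their hairpins. By the series text the TT-FHAgo2 cells of this pair are without Ago proteins, apart from the Ago2 that doxycycline induces. Files held 16433759 (A) and 30098249 (B) reads for the tagged IP, 17711795 and 18226922 for the untagged IP, 14956146 and 18579602 for the tagged input and 16664206 and 14474875 for the untagged input. The single libraries held 27829938 reads with doxycycline, 26542602 without it, 32255916 in wildtype and 78762632 in Dicer-null cells. A count of 0 allows a level of up to 0.0381 to 0.207 CPM (reads out of 1000000 in the file), depending on the library, for counting error only. P-values measure the spread between these libraries alone, since the labels do not say that replicates came from separate cultures.

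MiRNA hairpins took 54.5% ± 5.39 of all reads in the tagged IP and 11.1% ± 2.73 in the untagged IP (SD, n = 2 each), against 2.44% ± 0.895 and 3.34% ± 0.0330 in the inputs. The tagged IP therefore held 4.90 times the hairpin share of the untagged IP, or 6.35 times within replicate A and 3.88 times within replicate B; among reads of 18 to 26 nt it held 2.54 times. Reads from the first 200 nt of protein-coding transcripts, called promoter-proximal windows from here on, went the other way. They made up 0.112% ± 0.016 of the tagged IP and 0.404% ± 0.12 of the untagged IP (SD, n = 2 each), a ratio of 0.278 (0.254 within replicate A and 0.315 within replicate B). For both shares the ranges of the 2 groups did not touch, and the exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow. Reads outside hairpins, with 1 extra 5' or up to 2 extra 3' bases counted as hairpin reads, were 23.9% of the tagged IP and 83.7% of the untagged IP. As a share of those, windows took 0.470% ± 0.073 and 0.478% ± 0.10 (SD, n = 2 each; ratio 0.949 within replicate A and 1.03 within replicate B), and the ranges overlapped.

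**Figure D1:**
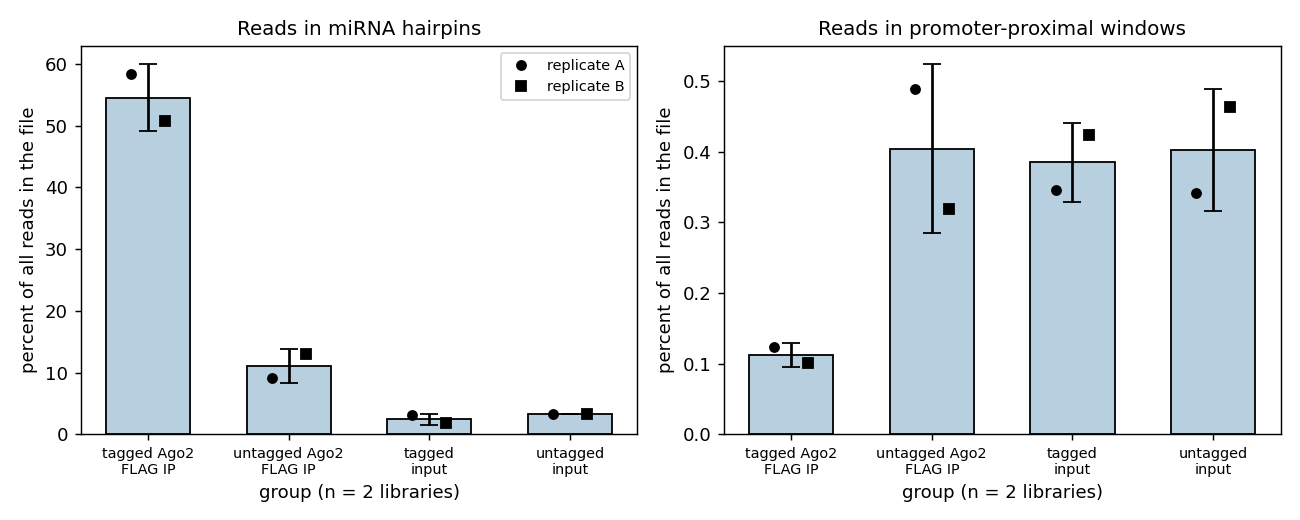
Percent of all reads that fell in miRNA hairpins (left) and in promoter-proximal windows (right) for the 4 groups; bars are means of 2 libraries, error bars are SD and points are libraries. The tagged IP has the highest hairpin share, 54.5%, and the lowest window share, 0.112%.

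The first comparison asks which small RNAs come down through the tag, by setting the tagged IP against the untagged IP. The miRNAs of the miR-290-295 cluster, which dominate in embryonic stem cells, were the most abundant: Mir294 (GRCm38 chromosome 7, 3220641 to 3220724) stood at 103380 ± 29221 CPM in the tagged IP and 26780 ± 4853 CPM in the untagged IP (SD, n = 2 each), a log2 fold change of 1.95 (SE 0.53, edgeR adjusted p 0.00290). Among 698 hairpins tested, 557 were higher and 63 lower in the tagged IP; DESeq2 called 586 higher and 5 lower, and these 5 were among the 63. At 10 CPM or more, 302 hairpins were higher and 12 lower of 319. The median log2 fold change of all hairpins was 2.42; it was 1.95 with TMM scaling and 4.04 with DESeq2.

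Families of stem cell and widely expressed miRNAs were higher in the tagged IP under library-total, TMM and DESeq2 scaling. The miR-290-295 list had 8 of 9 hairpins higher (median log2 fold change 2.25), and besides Mir294 it held Mir291a with 74234 CPM against 16250. All 6 of the miR-302 cluster, a marker of pluripotent and epiblast cells, were higher (median 2.24), as Mir302d shows with 91.9 CPM against 13.5. All 17 of the miR-17-92 cluster and its paralogs, which promote cell proliferation, were higher (median 2.60). Mir92-1 (chromosome 14, 115044427 to 115044506) reached 10550 CPM against 2140. The imprinted Dlk1-Dio3 cluster had 36 of 38 hairpins higher (median 2.44), among them Mir136 with 3757 CPM against 574, and 37 when adjusted over the list alone. All 19 of the rodent cluster in an intron of Sfmbt2 were higher (median 2.72). Under the naming minimum of 10 CPM this cluster held the largest named increases, with Mir466b-3 at a log2 fold change of 3.50 (113 CPM against 9.96) and Mir466f-3 at 3.41. The highest value in the fibroblast list was 4.58. In the let-7 family, which marks differentiated cells, 13 of 18 were higher and 5 were not called (median 2.10); TMM called 10 and DESeq2 17. For every hairpin list of at least 3 members but Dlk1-Dio3 the count adjusted over the list alone was the same as that over all hairpins.

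Most miRNAs made by unusual routes were higher as well. Mirtrons and hairpins that begin at a transcription start site, which bypass Drosha, had 8 of 9 higher (median 2.54); the last lay at −0.94 and TMM called it lower. Among the higher were Mir484 at 1443 CPM against 292 and Mir320 at 332 CPM against 45.3. Mir451a, cut by Ago2 itself instead of Dicer, was rare but higher, at 3.44 ± 1.85 CPM against 0.587 ± 0.287 (SD, n = 2 each; log2 fold change 2.53, edgeR adjusted p 0.00453). Of widely abundant miRNAs all 29 were higher (median 2.61), among them Mir96 with 13975 CPM. Among lists of other cell types, all 6 fibroblast hairpins (median 2.56), all 3 blood hairpins (2.44), the 1 muscle hairpin (3.27) and 3 of 4 neural hairpins (2.23) were higher. The fibroblast list held Mir22, with 4038 CPM in the tagged IP. The liver miRNA Mir122 was not called, at 0.767 CPM against 0.386 (edgeR adjusted p 0.205), though DESeq2 called it higher. Fry's test of a one-way shift gave adjusted p-values from 0.00619 to 0.0149 over the 17 lists with at least 3 members, window lists included. Fry does not set a list against other features, and most hairpins were higher, so this is not particular to these lists. Camera, which does, called no hairpin list different from other hairpins. Its adjusted p was 0.0914 or more for each, and 0.890 with the estimated correlation. Among the lower hairpins, Mir6236 stood at 15.1 ± 1.72 CPM against 102 ± 1.56 (log2 fold change −2.76). Snord43, a snoRNA gene that the annotation also holds as a miRNA, stood at 11.1 ± 11.01 CPM against 125 ± 131 (−3.50). DESeq2 called neither.

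Windows of highly transcribed genes were lower in the tagged IP when scaled to the library total. Of 933 windows, 801 were lower and 26 higher, and at 1 CPM or more 332 were lower and 14 higher of 366. All 71 ribosomal protein windows were lower (median log2 fold change −2.93): Rps12 fell from 24.6 CPM in the untagged IP to 2.14 CPM, and Rpl26 from 21.4 to 2.31. All 34 replication-dependent histone windows were lower (median −2.92), with Hist1h2bg at 0.637 ± 0.040 CPM against 12.1 ± 4.99 (SD, n = 2 each; log2 fold change −4.22, edgeR adjusted p 0.00187). All 22 housekeeping windows (median −2.90; Actb 1.39 CPM against 10.2, Ran 1.38 against 11.5), all 14 snoRNA host windows (−2.90; Nop56 1.67 CPM against 15.2) and all 14 pluripotency windows (−2.36; Trim28 1.90 CPM against 14.6, Klf2 0.495 against 3.44) were lower too. So were 7 of 8 immediate-early and stress windows (−2.84; Hsp90ab1 3.45 CPM against 28.1) and both small RNA pathway windows, Dgcr8 and Drosha (−2.36). No Polycomb-target developmental gene passed the filter, so 0 were tested. Counts adjusted over the list alone were the same for the lists of at least 3 members.

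These window calls rest on the scaling and on single libraries. The median of all windows was −2.64 with library totals and −3.11 with TMM (19 higher, 839 lower), but −1.07 with DESeq2 (34 higher, 3 lower) and −0.55 when scaled to reads outside miRNA hairpins (76 higher, 3 lower of 1491). With DESeq2 no ribosomal protein, pluripotency, housekeeping or stress window was called, and their medians stayed below 0 under all 4 scalings. Without the tagged IP library B edgeR called 0 windows, with 667 at an unadjusted p under 0.05; without the untagged IP library A it called 547, and without B 1642. Without the tagged input library A it called 1295, and without B 1274, as more windows passed the filter. Camera, which sets a list against all other windows, called the ribosomal protein (adjusted p 0.000178), histone (adjusted p 0.0372) and housekeeping windows (adjusted p 0.0438) lower than the rest, but the adjusted p was 0.890 for each with the estimated correlation. For the immediate-early list camera's sign was up while the median and mean were below 0.

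A few windows, 26 in all, were higher in the tagged IP. TMM called 19 of them, 11 were higher among windows without 1 dominant 5' end, and with each distinct sequence counted once edgeR called 0 of 553 windows higher and 398 lower (427 at an unadjusted p under 0.05). The most abundant was Cpsf4l, at 84.2 ± 9.50 CPM against 15.7 ± 7.20 (SD, n = 2 each; log2 fold change 2.42, edgeR adjusted p 0.00427) and 1.28 CPM in the tagged input. One 5' end gave 92.7% of its reads, from the 22-nt RNA TCTGTCCCACACACCCTCTGAC in the 5' UTR, exon 1 (GRCm38 chromosome 11, 113709961 to 113709982, minus strand); 2 annotated genes, Cpsf4l included, hold an 18-mer of it. Khk, the gene of ketohexokinase, stood at 78.2 ± 3.34 CPM against 14.5 ± 1.28 (log2 fold change 2.43), and 83.0% of its reads shared 1 5' end. Its main RNA was the 19-nt GGGGGGGGGCGGGGCCTCG, 78.2% of its reads. With reads of 22 nt or more 15 of the 26 windows were called higher. Chac1, a glutathione-degrading enzyme of the stress response, stood at 2.40 CPM against 0.279, and the histone chaperone gene Asf1b at 6.09 against 1.27. Tfap4 (4.97 CPM against 0.526) and Rab3gap1 (4.62 against 0.921) were also higher, but 336 and 701 annotated genes, themselves included, hold an 18-mer of their main sequences. Without the tagged IP library B edgeR called 0 of these windows.

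Window reads differed in size and position between the IPs. Reads of 20 to 24 nt, the size of Ago2 cargo, made up 38.6% ± 5.0 of window reads in the tagged IP and 20.2% ± 4.2 in the untagged IP (SD, n = 2 each), 24.3% in the tagged input and 25.3% in the untagged input. The ratio between the IPs was 1.91 (2.03 within replicate A and 1.82 within replicate B). A 5' T, which Ago2 cargo often carries, began 26.7% of window reads in the tagged IP and 16.0% in the untagged IP (2.09 times within replicate A, 1.45 times within replicate B). The Cpsf4l window weighs on both shares, by an amount not worked out here. It held 84.2 CPM in the tagged IP and 15.7 CPM in the untagged IP, with 92.7% of its reads from 1 5' end. Its main RNA of 22 nt begins with T. Read density in the window over that from its end to 1000 nt was 2.70 ± 0.080 in the tagged IP and 1.43 ± 0.082 in the untagged IP (SD, n = 2 each), and 6.20 and 7.24 in their inputs. Reads of 18 to 19 nt were 49.3% of window reads in the tagged input and 47.3% in the untagged input. The Itsn1 window, with 1 dominant 5' end and reads near 18 nt, was abundant in the tagged input. It weighs on the window share, the 18 to 19 nt share and the density there, by an amount not worked out here. Whether its reads come from the Itsn1 gene or from rRNA missing from the annotation was not tested. For each measure between the IPs the ranges did not touch, with an exact permutation p of 0.333. With each distinct sequence counted once, a 5' T began 23.3% and 17.9% (ratio 1.30), the ranges overlapped and p was 0.667. The density ratios were then 2.74 and 2.34 (ratio 1.17). Reads of 20 to 24 nt were then 33.8% in the tagged IP, 20.5% in the untagged IP and 31.4% in the tagged input, and the ranges of the tagged IP and its input overlapped (p 0.667).

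**Figure D2:**
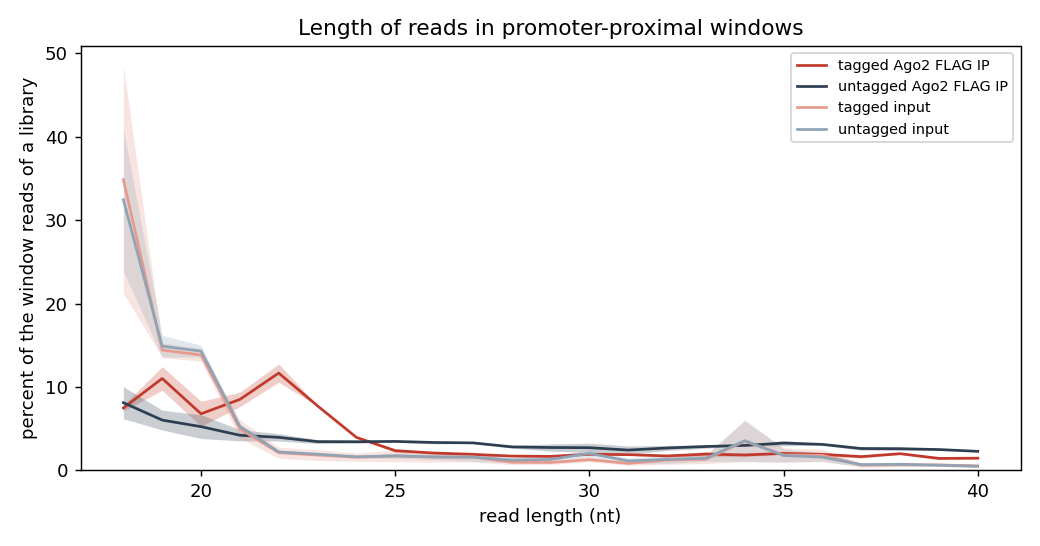
Percent of a library's promoter-proximal window reads at each read length from 18 to 40 nt, for the 4 groups; lines are means of 2 libraries and shaded bands run from the lower to the higher library. The tagged IP has a peak near 22 nt that the untagged IP and both inputs lack, and reads of 20 to 24 nt are 38.6% of its window reads.

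The second comparison, of the tagged IP with its own input, asks what the IP enriched from the starting RNA. MiRNAs rose by more than in the first comparison: Mir294 from 5414 ± 1160 CPM to 103380 ± 29221 (SD, n = 2 each; log2 fold change 4.26, SE 0.58, edgeR adjusted p 2.1e-06), Mir92-1 from 313 CPM to 10550 and Mir22 from 114 to 4038. Of 698 hairpins 583 were higher and 59 lower. All 9 of miR-290-295, all 6 of miR-302, all 17 of miR-17-92, all 18 of let-7, all 38 of Dlk1-Dio3, all 19 of the Sfmbt2 cluster and 28 of 29 abundant miRNAs were higher. With TMM the median of all hairpins went from 4.86 to 2.26, let-7 had 13 of 18 higher, and 1 abundant miRNA was lower. Of 9 made without Drosha 8 were higher and 1 was lower (−2.67), and Mir1249 rose from 1.62 to 144 CPM (log2 fold change 6.48). Mir5126 fell from 200.95 to 6.88 CPM (−4.86).

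Few windows were called against the input. Khk, Cpsf4l and Asf1b, also higher between the IPs, were among the highest. Their log2 fold changes were 7.21, 6.04 and 5.97 (edgeR adjusted p 7.2e-06, 6.2e-05 and 0.000141). Of 933 windows 32 were higher and 39 lower. The lowest were GC-rich reads near the 18 nt limit. The Itsn1 window fell from 1171 ± 819 to 22.1 ± 16.7 CPM (SD, n = 2 each). In it GGCTCCGGGACGGCCGGG and its extensions shared 1 5' end in 95.9% of reads. The Zfp654, Ube3c and Wtap windows fell by 4.86, 4.44 and 4.01 on the log2 scale. Reads of these windows were unique among annotated genes only. Whether they come from the named genes, or from rRNA or other sequence missing from the annotation, was not tested. Lower calls reached 2 of 71 ribosomal protein, 3 of 34 histone, 1 of 22 housekeeping and 1 of 14 snoRNA host windows and no pluripotency window. The split was 10 higher and 733 lower with TMM, 17 and 44 with DESeq2, and 431 and 11 when scaled to reads outside miRNA hairpins. Ribosomal protein windows had 16 of 72 higher in the last of these, where the median of all windows was 1.88 instead of −0.40. Leaving out 1 library left 25 calls (tagged IP A), 24 (tagged IP B), 34 (tagged input A) or 34 (tagged input B) in place of 71.

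The third comparison takes the gain of IP over input in tagged cells and subtracts that in untagged cells; tag and cell line go together here. MiRNA hairpins gained more in the tagged line in 418 of 698 cases and less in 37, and with DESeq2 in 495 and 2. Among the largest gains at 10 CPM or more was that of Mir185, with a log2 difference of 3.97 (SE 0.96, edgeR adjusted p 0.0134, n = 2 per group). Mir302d (3.81), Mir425 (3.71) and Mir22 (3.67) stood beside it, and Mir294 gained 2.61. Mir451a, rarer than that minimum, was called higher at 5.95. Its log2 fold change was 6.56 against its input and −3.42 between the tagged and untagged input, the latter not called. The size of its gain thus rests on very few reads in the tagged input. The highest values in the Sfmbt2 and fibroblast lists were 4.83 and 5.30. Between the inputs the lowest values in these lists were −2.39 and −2.80, and no member was called there. Larger gains were called for 8 of 9 hairpins of miR-290-295, 6 of 6 of miR-302, 17 of 17 of miR-17-92, 36 of 38 of Dlk1-Dio3, 17 of 19 of the Sfmbt2 cluster, 8 of 9 made without Drosha and 26 of 29 abundant miRNAs. In let-7 the count was 7 of 18, and Mirlet7a-2, at a log2 difference of 2.13, was not called (edgeR adjusted p 0.0743). With TMM the split was 163 to 54. Called higher were then 6 of 9 of miR-290-295, 4 of 6 of miR-302, 9 of 17 of miR-17-92, 23 of 38 of Dlk1-Dio3, 8 of 19 of the Sfmbt2 cluster, 5 of 9 made without Drosha (1 lower), 8 of 29 abundant miRNAs and 2 of 18 of let-7, with 2 of let-7 below 0. Without the untagged input library A, 155 hairpins were called, and without the tagged IP library B, 281.

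Among windows Khk alone gained more in the tagged line (log2 difference 4.29, SE 0.96, edgeR adjusted p 0.0498) and 55 gained less. The 55 included Hist1h2bg (−4.21), the RNA-binding protein gene Hnrnpk (−3.61), Ncl (−3.62), Ran (−3.15), 7 of 71 ribosomal protein windows, 6 of 34 histone windows, 5 of 22 housekeeping windows, 2 of 14 snoRNA host windows and 1 of 14 pluripotency windows. With reads of 22 nt or more, which leave out Khk's 19-nt main RNA, 0 gained more and 26 less. DESeq2 called 2 higher and 0 lower (63 at an unadjusted p under 0.05), and scaling to reads outside miRNA hairpins gave 7 higher and 0 lower. With the replicate code as a block the counts were 13 and 440. Each single library decided this count of 56: leaving out the tagged IP library A or B gave 1 or 0, the tagged input A or B 1 or 130, the untagged IP A or B 2 or 407, and either untagged input 0.

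Between the inputs of the tagged and untagged lines no feature was called. EdgeR called 0 of 698 hairpins and 0 of 933 windows, with 28 and 16 at an unadjusted p under 0.05, and DESeq2 called 0 and 0, with 17 and 7. The median log2 fold change was −0.33 for hairpins and −0.23 for windows. Members of the miRNA and window lists had 0 calls, Mir294 among them at 5414 CPM against 8557, but some lists leaned to 1 side: all 6 of miR-302 (median −1.32), 37 of 38 of Dlk1-Dio3 (−0.68) and Mir451a (−3.42) lay below 0. Lower values in the tagged input add to the gains of the third comparison. Without the tagged input library A edgeR called 4 hairpins lower, and without the untagged input library A it called 1 higher.

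The single libraries ask how far small RNAs depend on Dicer and on Ago2. With no replicates, the intervals are exact 95% limits for counting error only, and no spread between cultures is known. Hairpins took 21.1% of wildtype reads and 1.42% of Dicer-null reads, a ratio of 0.0673 (0.0671 to 0.0674); it was 0.0103 with reads of 20 to 24 nt and 0.433 with distinct sequences. Of 421 hairpins with at least 100 reads, 320 were at 0.25 of the wildtype level or less in Dicer-null cells and 3 were at least 4 times higher. Mir293 of the miR-290-295 cluster had 6515 reads against 891241 (ratio 0.00299) and Mir302b 17 against 69483 (ratio 0.000100). All 6 hairpins of miR-290-295, all 6 of miR-302, 16 of 17 of miR-17-92, 7 of 7 of let-7, 35 of 36 of Dlk1-Dio3, 15 of 15 of the Sfmbt2 cluster, 26 of 27 abundant miRNAs and 4 of 5 made without Drosha were at 0.25 or less. Among 10000 random lists of like abundance, the median log2 ratio of the Sfmbt2 cluster (−10.47) lay at percentile 0.05 and that of miR-17-92 (−10.56) at percentile 0.705. Mir5121, at a ratio of 0.703, and Mir6539, at 4.03, did not go with the rest.

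Windows did not fall with the hairpins. They took 0.305% of Dicer-null reads and 0.216% of wildtype reads, a ratio of 1.41 (1.40 to 1.42). The ratio was smaller with miRNA reads left out of the total. Protein-coding transcripts outside the windows also took more, 7.07% of Dicer-null and 4.34% of wildtype reads, so the rise was not particular to windows. Of 386 windows with at least 100 reads, 2 were at 0.25 or less: Cpsf4l, with 25 reads against 233 (ratio 0.0439), and Pfkp (0.234). Alpl, the alkaline phosphatase gene, was 12.3 times higher with 2105 reads against 70, and Gpx1, Mt2 and Actb were 7.55, 5.30 and 3.80 times higher. The median log2 ratio was 0.25 for 35 ribosomal protein windows, percentile 0.065 of random lists, while all windows had a median of 0.66. Pluripotency (0.83), histone (0.73), housekeeping (0.77), snoRNA host (0.51) and immediate-early windows (0.65) lay inside the range of random lists.

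Doxycycline is meant to switch on Ago2 in the TT-FHAgo2 line, and miRNA hairpins were higher with it, while reads of Ago2 transcripts stood at 2.95 CPM with it and 2.83 CPM without. Hairpins took 10.3% of reads with doxycycline and 1.30% without, a ratio of 7.91 (7.88 to 7.94); it was 27.2 with reads of 20 to 24 nt and 1.32 with distinct sequences. Of 327 hairpins with at least 100 reads, 243 were at least 4 times higher and 0 were at 0.25 or less. Mir21a had 130835 reads against 1154 (ratio 108), Mir293 was 76.0 times higher, Mir127 of the Dlk1-Dio3 cluster 89.7 times, Mir484 79.4 times and Mir92-1 13.5 times. Every measured hairpin of miR-290-295 (6), miR-302 (3), miR-17-92 (16), let-7 (7), Dlk1-Dio3 (35) and the Sfmbt2 cluster (10) was higher, as were 25 of 26 abundant miRNAs and 4 of 5 made without Drosha, with 1 lower in each of these lists. The Sfmbt2, Dlk1-Dio3 and miR-17-92 medians (6.36, 5.97 and 6.24) lay at percentiles 99.8, 99.3 and 98.8 of random lists. Windows had a ratio of 0.864 (0.854 to 0.874). Of 107 windows, Cpsf4l was the only 1 at least 4 times higher, with 225 reads against 5 (ratio 42.9, interval 18.1 to 133), and Nanog was among the lowest with 35 against 95 (ratio 0.351).

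The line without doxycycline was set against wildtype cells as well, and miRNA hairpins were low in it. These are different cell lines, and the labels do not say whether they share a parental line, so line and Ago2 cannot be parted here. The hairpin ratio was 0.0616 (0.0614 to 0.0618), or 0.0174 with reads of 20 to 24 nt and 0.784 with distinct sequences, and 317 of 386 hairpins were at 0.25 or less and 2 at least 4 times higher. Mir302d was at 0.000123 of its wildtype level, Mir17 at 0.000982, Mir293 at 0.00697 and Mir142 at 0.346. The Sfmbt2 (−8.82), miR-17-92 (−8.34) and miR-302 (−8.96) medians lay at percentiles 0, 0.03 and 0.38 of random lists. Windows had a ratio of 1.09 (1.08 to 1.10), which became 0.870 when miRNA reads were left out of the total. Alpl (7.50), Actb (4.78) and Nanog (2.46) were higher and Apoe (0.356) and Cpsf4l (0.0261) lower. Among the 4 windows at 0.25 or less, mt-Nd3 (0.00263) and Homer3 (0.00816) had reads with 1 substitution in that library, at 99.7 and 3.24 CPM. Across 327 hairpins measured in both pairs, the Dicer-null log2 ratio and the doxycycline log2 ratio had r −0.81 and rho −0.68, and 241 were both at 0.25 or less and at least 4 times higher. Across 105 windows r was −0.68 and rho −0.34, with Cpsf4l the only window to meet both limits, or either of them. It lies far from the other windows and weighs on r, by an amount not worked out here. These are correlations across genes, which are not independent replicates. Whole-transcript reads of Dicer1 stood at 1.56 CPM in Dicer-null and 1.67 CPM in wildtype cells, and those of Ago2 at 2.95 CPM with and 2.83 CPM without doxycycline, so these short reads show neither the loss nor the induction that the labels name.

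**Figure D3:**
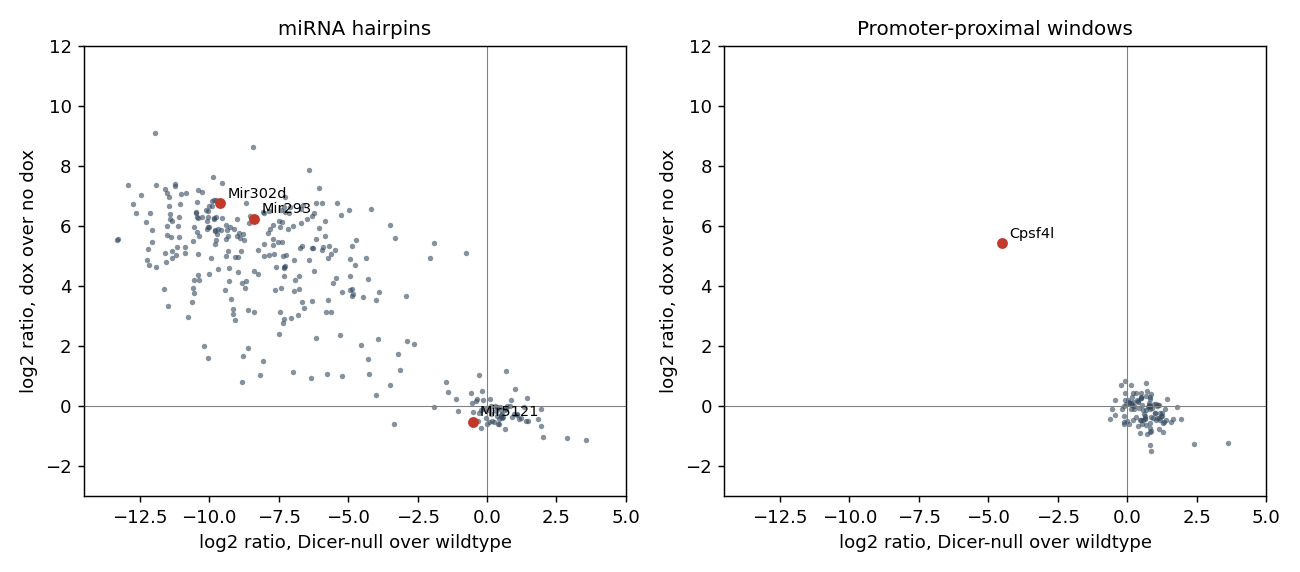
Log2 ratio of read shares in Dicer-null over wildtype cells (horizontal axis) against that in TT-FHAgo2 cells with over without doxycycline (vertical axis), for 327 miRNA hairpins (left) and 105 promoter-proximal windows (right), each with at least 100 reads in both pairs; each point is 1 feature from single libraries. Most hairpins lie at the upper left, and Cpsf4l is the only window there.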

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

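Of the tests below, the one on the same most abundant sequence was fixed before its result was seen; the tests on scaling, the share outside miRNA hairpins (with its limits), 18-mers, Dicer and doxycycline, and single-base changes were chosen after their results were seen, and so was the minimum of reads that leaves Gm47283 open.

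The gain of IP over input differed between tagged and untagged cells for 455 miRNA hairpins and 56 windows, by edgeR's test of the difference itself; between the IPs, 801 windows were lower in the tagged one. If miRNA reads only fill more of that library, the 801 windows should keep their share of reads outside miRNA hairpins: the tagged IP held 0.557 of the untagged share (0.631 within replicate A, 0.470 within replicate B), and the ranges did not touch. Dilution by miRNA reads may thus be part of the cause. The median of all windows, −2.64 by library totals, lay nearer to no change when scaled to reads outside miRNA hairpins. How much dilution accounts for is not settled, since the 801 windows were picked for being lower and unmatched reads in that total were not sorted. Less RNA that sticks without the tag stays open too: on that scale the median log2 fold change of 1491 windows was −0.55, with 76 called higher and 3 lower, but no outside standard says where 0 lies, and the 2 explanations cannot be told apart here. Binding to tagged Ago2, the biological difference of the design, was not tested apart from these.

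The 26 windows higher in the tagged IP, such as Cpsf4l, Khk and Chac1, were weighed next. Copies of 1 molecule amplified in 1 library were not what most showed, since 20 of the 26 had the same most abundant sequence in both tagged IP libraries. The call itself favours windows that are high in both, so this outcome was partly set by the selection. Copies of the same sequence in both libraries stay open, as the higher calls were lost with each distinct sequence counted once. Reads from repeats elsewhere in the genome stay open: 6 of the 26 share an 18-mer with another annotated gene, namely Cpsf4l, Tfap4, Rab3gap1, Telo2, Sipa1 and Asap2, and unannotated copies could not be searched. Small RNAs held by Ago2 and made by Dicer stay open too: the 2 windows with 20 or more reads of 20 to 24 nt in both pairs of single libraries, Cpsf4l and Rab3gap1, were both higher with doxycycline and in wildtype, but both are among the 6 above. With 2 windows measurable of 26, this cannot be settled, and Khk's main RNA of 19 nt is shorter than the reads it counts.

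Reads left unmatched in the main measurement carried 2 of the windows that seemed lost in the library without doxycycline. For mt-Nd3, reads with 1 substitution stood at 99.7 CPM there and 3.94 CPM in wildtype, with T3C counted from the first base of its main sequence (GRCm38 chromosome M, 9461), and for Homer3 at 3.24 and 0.186 CPM, with A17G (chromosome 8, 70289353). Relative to the wildtype level of the reference sequence these are 1.39 and 0.584, so a strain variant against the reference is a candidate explanation for both. The same line with doxycycline had 4014 reads with T3C against 3 of the reference for mt-Nd3. For Homer3 it had 41 with A17G against 1. Dicer-null cells carried the reference, with 8987 reads for mt-Nd3 and 771 for Homer3. Cpsf4l and Pfkp are another matter, as reads with 1 substitution came to 0 of the wildtype level in the library without doxycycline and in the Dicer-null library, which argues against a variant there. The same test gave 0 for Gm47283, with too few wildtype reads to decide; no biological explanation was tested for mt-Nd3, Homer3, Pfkp or Gm47283.

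In data outside the main counts, reads with 1 extra 5' base reached 32.8% of hairpin reads in the untagged IP library B, and they were 10.2% or more in all 8 circularized libraries against 0.653 to 4.59% in the 4 ligated ones. Counting them left the miRNA calls between the IPs at 580 higher and 66 lower.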

How the results depend on the processing

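Scaling to reads outside miRNA hairpins, reads of 22 nt or more, windows without 1 dominant 5' end, 1 extra 5' base and the 20 to 24 nt hairpin ratios were chosen after the data were seen; the rest was planned. Of 212 summary values under an alternative, 125 stayed within 1.5 times the count, or within the spread or counting interval of a ratio. For counts only the total called was compared, not its split into higher and lower. Of 1370 values of the 80 named gene contrasts, 1213 kept direction and call, 151 were no longer called, 6 were called only there and 0 changed sign. The cause was not tested except where named. The number of hairpin calls between the IPs and against the input stayed within 1.5 times under every alternative run, but not each call: between the IPs DESeq2 kept 553 of 557 higher and 5 of 63 lower, and for the difference of gains 415 of 418 and 2 of 37. For the latter TMM gave 217.

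Window calls moved with most choices. Between the IPs (827) they were 37 with DESeq2, 455 with a window to 100 nt, 257 with reads of 18 to 26 nt, 398 with distinct sequences, 0 higher and 398 lower (these 3 test fewer windows), and 79 scaled to reads outside miRNA hairpins. Against the input (71) they were 743 with TMM, 37 without the filter, 0 with distinct sequences (edgeR, 48 at an unadjusted p under 0.05), 442 scaled to reads outside miRNA hairpins, 32 with reads of 22 nt or more and 27 without dominant 5' ends. For the difference of gains (56) they were 665 with TMM, 2 with DESeq2, 0 without the filter (edgeR, 1050 unadjusted), 2 with reads of 18 to 26 nt, 85 with sequences in up to 10 genes, 0 with distinct sequences (147 unadjusted), 7 scaled to reads outside miRNA hairpins, 26 with reads of 22 nt or more and 97 without dominant 5' ends.

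With the replicate code as a replicate block, window calls went to 112 against the input and to 453 for the difference of gains, and no other count moved by more than 1.5 times. Deviations of the paired libraries from their group means correlated positively for every pair of groups (0.0672 to 0.481 for hairpins, 0.103 to 0.333 for windows), so the code carries some shared variation.

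Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the rest, gave 490 to 670 hairpins between the IPs, 631 to 721 against the input, 155 to 462 for the difference of gains and 0 to 4 between the inputs. For windows the ranges were 0 to 1642, 24 to 98, 0 to 407 and 0 to 0. The ratio between the IPs ranged from 4.18 to 5.93 for the hairpin share, 0.230 to 0.352 for the window share, 1.67 to 2.23 for window reads of 20 to 24 nt, 1.28 to 2.42 for a 5' T and 1.82 to 1.97 for the density ratio.

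Between the IPs, reads of 18 to 26 nt gave a hairpin share ratio of 2.54 and a window share ratio of 0.215; scaled to reads outside miRNA hairpins the window ratio was 0.982. Distinct sequences gave 1.65 for window reads of 20 to 24 nt and 1.17 for density, and for a 5' T 1.30 with ranges that overlap. With the estimated correlation camera called 0 lists in place of 3.

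In the single libraries hairpin ratios for Dicer-null over wildtype, doxycycline over none, and none over wildtype were 0.0103, 27.2 and 0.0174 with reads of 20 to 24 nt, 0.0179, 20.5 and 0.0230 with 18 to 26 nt, 0.0605, 7.83 and 0.0598 with snoRNA reads as the total, and 0.433, 1.32 and 0.784 with distinct sequences. Window ratios were 1.13, 0.9505 and 0.870 with the total without miRNA reads, the last on the other side of 1. They were 1.30, 0.876 and 1.03 with 18 to 26 nt and 1.19, 0.844 and 1.17 with distinct sequences. Hairpins at 0.25 or less numbered 97 (Dicer-null) and 32 (none over wildtype) with distinct sequences, and 2 (doxycycline) with a minimum of 20 reads. Windows at 0.25 or less numbered 11, 10 and 14 with that minimum, which admits more windows, 1 (Dicer-null) and 2 (none over wildtype) with 18 to 26 nt, and 3 (doxycycline) with distinct sequences. With 2 libraries per group and the assumed spread of the simulation, 13 of 50 simulated 2-fold changes in hairpins and 11 of 50 in windows were recovered.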

Other observations

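Hairpin reads differed in length with the state of the miRNA pathway. Reads of 20 to 24 nt, the length of mature miRNAs, were 93.9% of hairpin reads in the tagged IP, 93.5% in the untagged IP and 83.9% and 84.1% in the inputs. They were 91.8% in wildtype cells and 89.2% with doxycycline but 25.9% without it and 14.05% in Dicer-null cells, so most hairpin reads left in those libraries were not of miRNA length. Mir5121 differed less than most hairpins, with a ratio of 0.703 in Dicer-null cells and 0.700 with doxycycline. The liver miRNA Mir122 had 293 reads in Dicer-null cells and 35 in wildtype cells, a ratio of 3.43 (2.41 to 5.02).

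Structural RNAs took smaller shares of all reads in the tagged IP than in the untagged IP. MiRNA hairpins filled 58.3% (replicate A) and 50.7% (replicate B) of the tagged IP, against 9.19% and 13.1% of the untagged IP. This leaves less room for other classes and weighs on the ratios below, by an amount not worked out here. SnRNA took 0.223% of reads against 2.91% (ratio 0.0660 within replicate A and 0.0870 within replicate B), rRNA 0.817% against 5.34% (0.141 and 0.177) and snoRNA 0.0622% against 0.324% (0.158 and 0.253), each with an exact permutation p of 0.333. In the 4 ligated libraries snoRNA took 14.04 to 15.6% of reads. Window reads with a 5' G were 54.2% and 50.6% in the inputs and 22.9% and 18.4% in the tagged and untagged IPs. The abundant reads counted for the Itsn1 window, whose origin was not tested, begin with G. They weigh on the share in the tagged input, by an amount not worked out here.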
